A study of Mus musculus with 2 samples.

How the data were processed

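The material was lung tissue from mice bearing tumours of Lewis lung carcinoma, a mouse lung cancer cell line, here carrying the surface marker Thy1.1. Per the labels, 2 lung sections were imaged by MERFISH on the Vizgen MERSCOPE platform, which reads single RNA molecules in place through combinatorial barcodes. Each section was measured for 287 genes and 28 blank barcodes, which match no gene and give the rate of false decoding. The sections form 1 group with n = 2. The labels do not say that the lungs came from separate mice. The main fits below take section as a term. Their p-values therefore measure how far differences within a section disagree between these 2 sections, and not the spread between mice.

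The deposited tables give whole-number counts of transcripts per cell and barcode, made by the authors from the decoded images and a cell segmentation. Per the file headers, other files hold the centre position and volume of each cell and the position, plane and barcode of each detected transcript. The segmentation model, the decoding software and their settings are not given in the sources used here. Transcripts per gene inside cells were compared with those detected over 7 image planes, and transcripts of all cells were added per section to give the depth. Cells held 4310688 gene transcripts in section 1 and 6081842 in section 2. The images themselves and the cell outlines were not used here.

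Cells with at least 20 gene transcripts were kept. Counts were divided by the cell's total, multiplied by the median total and put on the log(1 + x) scale. Principal components (30) were computed over a random subsample of 20000 cells per section with seed 1, a graph of 15 nearest neighbours weighted by shared neighbours was built, and Leiden clustering was run at a resolution of 1.0. Every other cell took the most frequent cluster of its 15 nearest subsampled cells. Clusters of fewer than 20 subsampled cells were dissolved in the same way. This gave 19 clusters, which were named from 24 lists of cell type markers. A list was eligible where at least 3 of its markers stood at 1.5 times or more the mean of all other cells and above a minimum share of the cells' transcripts. Among eligible lists the name went to that with the highest mean log2 fold of its 3 best markers, and a cluster stayed unnamed where its 10 leading genes held none of those markers or more markers of another list. The suffix "-like" marks that names rest on RNA markers alone. Shares are percentages of kept cells, with exact (Clopper-Pearson) 95% binomial intervals per section, which cover counting error only. No doublet caller was run.

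Tumour zones were drawn on a grid of 10 µm squares. The densities of tumour-like cells and of all cells of named types were smoothed with a Gaussian of 30 µm, and squares where tumour-like cells made up at least 0.5 of the smoothed density were joined into nodules. A nodule needed at least 100 tumour-like cells. The margin zone reached 100 µm outward from a nodule, and the distant zone began at 250 µm. Inside nodules, tumour-like cells within 100 µm of the edge formed the rim and deeper ones the core.

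Cell numbers per zone and section (6 sums) were compared in edgeR quasi-likelihood models with zone and section as terms, with all kept cells other than tumour-like ones as the library. Transcripts were added per gene over the cells of each type, zone and section, for types with at least 50 cells in each sum. These sums were compared in edgeR with TMM scaling, filterByExpr and the same terms, since zones of 1 section are not independent of each other. With 6 sums, edgeR takes most of its estimate of spread from all genes together. Core and rim of tumour-like cells were compared in the same way over 4 sums. Fold changes are log2 with the standard error of the fit, p-values are two-sided and Benjamini-Hochberg adjusted, and 0.05 was the threshold. Fold changes per section use a prior count of 0.5. Gene lists (17 for processes, and the 24 for cell types) were tested where at least 4 members were measured, with limma's camera at a preset correlation of 0.01 and again with an estimated correlation.

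A gene was called spill-prone where another named type carried at least 3 times the mean count per cell of the tested type in the zone where the gene was higher. Unnamed clusters did not enter this rule, so genes carried mainly by them could go unmarked. Leading genes of such clusters include Cd24a, Vegfa, Cxcl9 and Cxcl10. The genes named for each comparison were fixed by rule. They are the 8 with the largest change in each direction among genes past the threshold, with the same direction in both sections, at least 50 counts per sum on average and not spill-prone. To these come 3 spill-prone genes per direction, 2 to 4 members per gene list that passed the threshold, and a fixed set of immune and tumour genes whatever their result. Thy1 and Spp1 of that set were not analysed here, so the Thy1.1 mark was not used to tell tumour cells. The types described gene by gene are the 5 most numerous in the tumour zone other than tumour-like cells.

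Neighbours were the kept cells within 30 µm of a tumour-like centre. Their number per type was divided by the mean over 100 random relabellings of cell types within the zones, and the log2 ratio is given per section and as mean ± SD. No p-value was computed for it.

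Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The fits were tested on simulated data with the real depths. For macrophage-like cells (285 genes) 20% of genes changed by 2-fold and 90% of those changed by 4-fold were recovered, for neutrophil-like cells (277 genes) 25% and 84.2%, and for endothelial-like cells (255 genes) 15% and 85%. The values were 10% and 85% for dendritic-like cells (279 genes), 50% and 95% for T-like cells (273 genes), and 10.5% and 30% for core against rim (279 genes). Unchanged genes were called in T-like cells alone, where 2 were (0.858%). Random labels gave a log2 neighbour ratio of at most 0.06 in size, cells placed beside others gave 0.22, and a simulated disc was found with 98.0% of its area. The disc held a larger share of tumour cells than the nodules of these data. Its value therefore does not show how well nodules of a lower share are drawn.

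The groups, tests, thresholds, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The exact scoring of names and the use of named types alone in the smoothed share were settled after the clusters had been seen and before any zone comparison: 3 ways of scoring names, 4 ways of drawing zones and 4 ways of joining clusters by profile were looked at. Alternatives covered the transcript minimum (10 and 50), cluster resolution (0.5 and 2.0), scaling by cell volume, the share (0.3 and 0.7) and smoothing (15 and 60 µm) of the zones, the start of the distant zone (100 and 500 µm), and the rim (50 and 150 µm). They also covered neighbour radius (15 and 50 µm) and relabelling over the whole section, DESeq2, library size only, no filter on low counts, no section term, sums thinned to equal depth, transcripts within 3 µm of the cell centre, and other libraries for cell numbers. Alternatives chosen after seeing the data were tumour zones that include the unnamed clusters with a tumour profile (Pearson r of at least 0.85 across genes with a tumour-like cluster), a share among all kept cells, a library of named types only, removal of cells within 10 µm of a tumour-like or tumour-profile centre, each macrophage-like and endothelial-like cluster alone, and neutrophil-like cells divided by their class at a minimum of 50 transcripts and at resolution 2.0. Nothing was left out of the sections; cells under the minimum and transcripts outside cells entered no comparison.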

Results

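MERFISH images of 2 sections of mouse lung carrying Lewis lung carcinoma tumours were analysed, 1 group with n = 2. The series is about the immune environment of this lung tumour model. The comparisons asked which cell types the sections hold, where the tumour lies, which cell types are depleted or enriched there, which genes differ in those cells between tumour and distant lung, and how tumour cells differ from the core to the rim of a nodule. Section 1 held 123573 cells, of which 54780 (44.3%) had at least 20 transcripts and were kept. Section 2 held 165382 cells, of which 82904 (50.1%) were kept. Kept cells carried a median of 54 transcripts from 31 genes in section 1 and 50 transcripts from 30 genes in section 2. The genes of the panel gave 4310688 transcripts inside cells in section 1 and 6081842 in section 2. The mean gene had 20.04 times the counts of the mean blank barcode in section 1 and 19.3 times in section 2, and 84 and 80 genes lay under 3 times the mean blank.

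Tumour-like cells were the largest named population, with 20.2% ± 3.4 (SD, n = 2) of kept cells, followed by macrophage-like cells with 13.1% ± 3.0. Endothelial-like cells made up 10.1% ± 1.5, dendritic-like cells 8.1% ± 0.4, T-like cells 7.1% ± 0.3, neutrophil-like cells 6.4% ± 3.2 and alveolar type 2-like cells, the surfactant-producing epithelium, 5.6% ± 2.4. Fibroblast-like cells made up 4.6% ± 0.2 and B-like cells 2.5% ± 0.5. The T-like cluster had the plasma-cell genes Igha and Jchain among its leading genes, so it may not hold T cells alone. The larger dendritic-like cluster was led by H2-Eb1, H2-Aa and Itgax but also had C1qa, Cx3cr1 and Cd72 among its leading genes. These also led a macrophage-like cluster, so the dendritic-like class may not hold dendritic cells alone. Neutrophil-like cells were 4.13% (exact 95% interval 3.97 to 4.30) of section 1 and 8.60% (8.41 to 8.79) of section 2. Macrophage-like cells were 11.0% (10.7 to 11.2) and 15.2% (14.99 to 15.5), and tumour-like cells 17.8% (17.5 to 18.2) and 22.6% (22.3 to 22.9). For tumour-like cells the order turned at resolution 0.5, with 39.0% and 29.2%, and with the unnamed clusters of tumour profile added, with 40.5% and 33.7%. Alveolar type 2-like cells were more frequent in section 1, with 7.25% (7.03 to 7.47) and 3.90% (3.77 to 4.04). The shares of the other types were, in section 1 and section 2, 9.07% (8.83 to 9.32) and 11.1% (10.9 to 11.3) for endothelial-like, 7.81% (7.59 to 8.04) and 8.43% (8.24 to 8.62) for dendritic-like, 6.95% (6.74 to 7.17) and 7.33% (7.15 to 7.51) for T-like, 4.78% (4.61 to 4.96) and 4.49% (4.35 to 4.64) for fibroblast-like, and 2.16% (2.04 to 2.28) and 2.81% (2.70 to 2.92) for B-like cells.

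Tumour-like cells fell into a pair of clusters split by section. The cluster led by Mki67, Hmmr and Nusap1, genes of dividing cells, with the proteases Plau and Mmp12, had 90.5% of its 9489 cells in section 1. The cluster led by Ly6a, Csf1, Egln3, Il1rl1 and Cd44 had 6.22% of its 19037 cells there. A further 22.2% ± 9.6 of kept cells stayed unnamed, 29.0% (28.6 to 29.4) in section 1 and 15.5% (15.2 to 15.7) in section 2. Of the 6 unnamed clusters, 4 resembled tumour-like cells, with Pearson r across genes from 0.903 to 0.955, where genes are not independent replicates. In section 1 and section 2 these held 13.1% and 0.823% of kept cells (cluster 8), 2.19% and 5.92% (cluster 11), 5.91% and 2.93% (cluster 12), and 1.48% and 1.38% (cluster 17). Cluster 17 was led by Cxcl10, Ifit1, Rsad2 and Ifit3, genes induced by interferon, and cluster 12 by Ptgs2, Csf3, Ccl2 and Cxcl5, mediators of inflammation. Cluster 8 was led by Lrrc15, Mmp12, Il1r1, Prrx1 and Pdgfra, and cluster 11 by Col6a2, Aspn, Tcf4 and Pdgfra. Col6a2 and Pdgfra were also among the leading genes of the fibroblast-like cluster. The correlation therefore does not settle whether clusters 8 and 11 are tumour or stroma. The other 2 held 4.61% and 2.34% (cluster 14, with the epithelial genes Epcam, Sox2 and Cbr2) and 1.78% and 2.06% (cluster 16, with Vegfa and Pdpn).

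**Figure D1:**
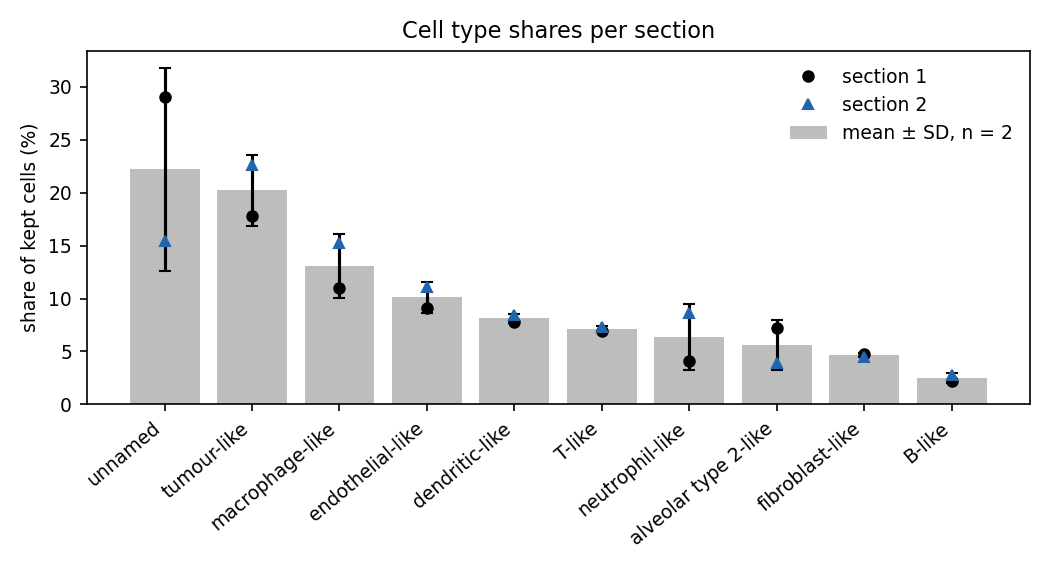
Share of kept cells per cell type (vertical axis, percent), with bars for the mean of the 2 sections, whiskers for the SD (n = 2), circles for section 1 and triangles for section 2. Tumour-like cells stand highest among named types at 17.8% and 22.6%, and unnamed cells range from 29.0% in section 1 to 15.5% in section 2.

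The tumour lay in a few ragged patches, here called nodules, in both sections. Section 1 had 4 nodules covering 1.101 mm² (11.4% of 9.67 mm² of tissue) and section 2 had 5 covering 1.18 mm² (9.11% of 12.9 mm²). The mean was 4.5 ± 0.71 nodules and 1.14 ± 0.053 mm² per section (SD, n = 2). The deepest point of a nodule lay 149 µm from its edge in section 1 and 110 µm in section 2. Nodules held 36.8% of the tumour-like cells of section 1 and 35.0% of those of section 2. The distant zone held 2559 and 2822 tumour-like cells, 8.80% and 7.64% of its cells. It was thus not free of tumour-like cells, and it also held cells of the unnamed clusters of tumour profile. In section 1 and section 2 these were 1118 and 256 of cluster 8, 917 and 2834 of cluster 11, 1538 and 518 of cluster 12, and 499 and 385 of cluster 17. Area depended on the rule: with a share of 0.3 it was 3.10 mm² per section and with 0.7 it was 0.0508 mm². With the unnamed clusters of tumour profile counted as tumour it was 2.54 mm².

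**Figure D2:**
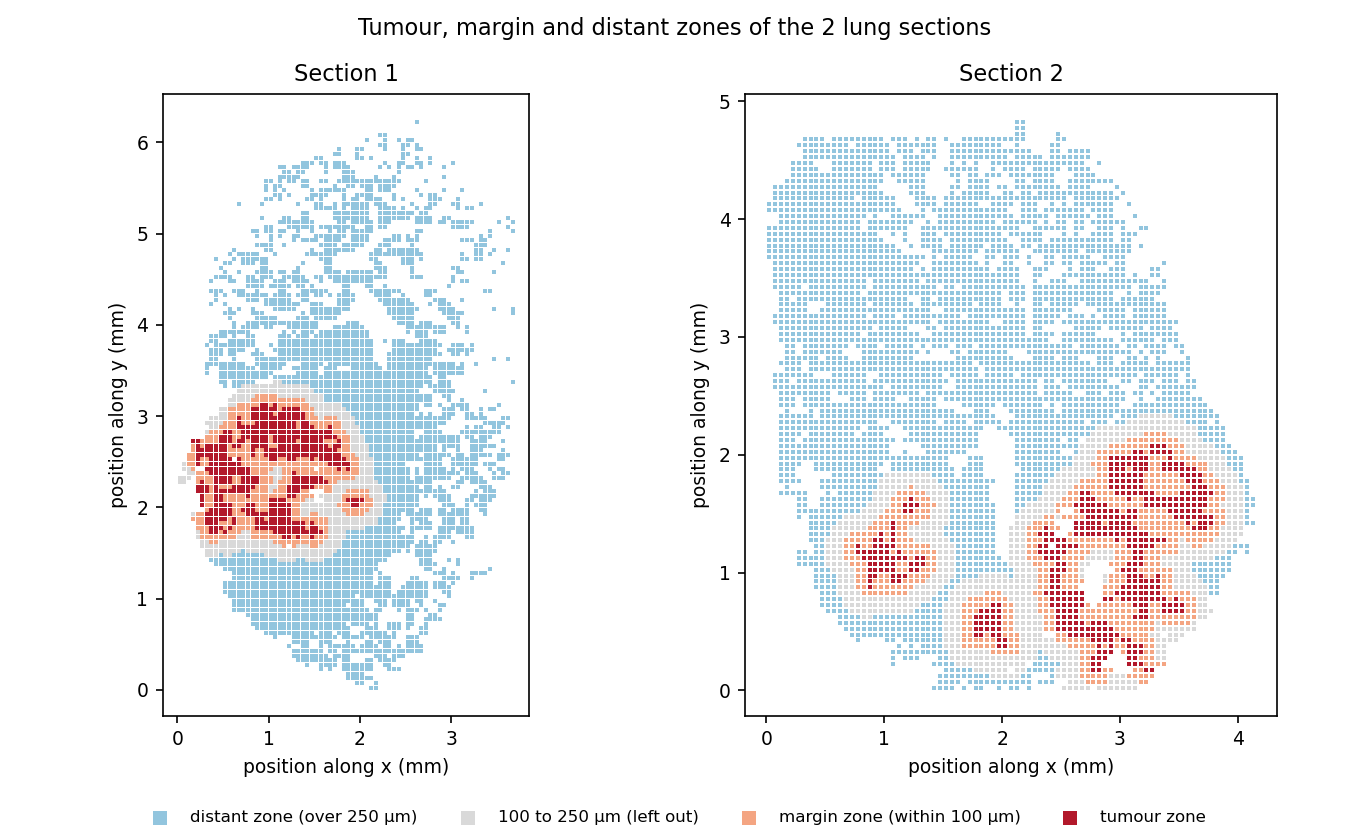
Maps of both sections (axes in mm) with squares coloured by zone: tumour, margin within 100 µm of a nodule, tissue between 100 and 250 µm that entered no comparison, and distant lung beyond 250 µm. The 4 nodules of section 1 and the 5 of section 2 cover 11.4% and 9.11% of the tissue.

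B-like cells were almost absent from the nodules. Section 1 had 4 B-like cells in the tumour zone and 1091 in the distant zone, and section 2 had 16 and 2002. Their density was 3.63 and 13.6 per mm² in the tumour against 172 and 245 in distant lung. Among cells other than tumour-like ones their number fell by 4.82 on the log2 scale (SE 0.75, edgeR adjusted p = 6.32e-05; −5.77 in section 1 and −4.12 in section 2). They also fell by 3.32 in the margin (SE 0.67, edgeR adjusted p = 0.00110; −3.69 and −2.89). Both calls were made under each of the alternatives run for them, other libraries, other zones, DESeq2 and the fit without the section term included. B-like cells count in the density against which the share of tumour-like cells is taken, so an area dense in them cannot be a nodule. Every alternative kept such a share, so how much of the fall follows from this rule was not tested.

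No other cell type passed the test in either zone. Macrophage-like cells had log2 0.84 in the tumour (SE 0.61, adjusted p = 0.247; 0.23 and 1.53) and 1.01 in the margin (0.45 and 1.67). T-like cells had −1.13 (adjusted p = 0.174), fibroblast-like cells −1.27, endothelial-like cells −1.17, alveolar type 2-like cells −0.87 and dendritic-like cells −0.78 in the tumour. Neutrophil-like cells had −1.49 in section 1 and 1.14 in section 2. In the margin the values were −1.27 for fibroblast-like, −1.09 for endothelial-like, −0.71 for T-like, −0.16 for dendritic-like, 0.26 for neutrophil-like and 0.51 for alveolar type 2-like cells. Density of macrophage-like cells was 662 and 1118 per mm² in the tumour and 488 and 400 in distant lung. In section 1 the tumour zone also held 3164 cells of the unnamed cluster 8, which count in the library. With named types alone as the library macrophage-like cells passed the test at 1.41, with TMM factors at 1.91, with a share of 0.3 at 1.61, with a minimum of 10 transcripts at 1.16 and with wider tumour zones at 1.94. Endothelial-like and fibroblast-like cells passed it as lower with DESeq2 (−1.17 and −1.26), a share of 0.3 (−1.41 and −1.66) and a minimum of 10 transcripts (−1.54 and −1.61), and 7 types did with all cells as the library. The last result follows largely from the design, since tumour-like cells define the tumour zone and there count in the library. Neutrophil-like cells passed as higher in the tumour with a minimum of 10 transcripts (1.48) and wider tumour zones (1.12). With the minimum of 10 the class also held a cluster of 4704 cells led by Hmox1, Ptgs2 and Il1rl1, and of its 4023 cells kept in the main setting 64.3% were macrophage-like there. In the margin dendritic-like cells turned to 0.93 with wider tumour zones.

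The macrophage-like class pooled clusters 2 and 13, whose shares of it differed between zones. In the tumour zone 36 of 285 genes were higher and 37 lower than in distant lung (edgeR, with 130 at an unadjusted p under 0.05). Folr2, a folate receptor of resident and tumour macrophages, rose by log2 1.68 (SE 0.30, adjusted p = 0.0168; 1.39 and 1.92). The mannose receptor Mrc1 rose by 1.27, the transcription factor Maf by 1.31, Ms4a7 by 1.57, Cd72 by 1.68, the tetraspanin Cd81 by 1.41, the urokinase Plau by 1.33, and Nusap1 and Mcm2, genes of dividing cells, by 1.49 and 1.40. Marco, a scavenger receptor of alveolar macrophages, fell by 4.09 (SE 1.12, adjusted p = 0.0466; −6.50 and −1.84). Gpnmb fell by 2.70, the neutrophil attractant Cxcl2 fell by 2.56, the protease Ctsk fell by 2.55, the proton pump subunit Atp6v0d2 fell by 2.42, the chitinase-like Chil3 fell by 2.27, Cd24a fell by 2.15 and the angiogenic factor Vegfa fell by 1.76. Cd24a was a leading gene of unnamed cluster 14, with 1 and 4 cells in the tumour zone and 2395 and 1859 in the distant zone. Vegfa was one of cluster 16, with 24 and 13 against 897 and 1525. The spill rule left these clusters out, and their RNA was not tested as a source.

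Grouped by the fixed lists, 6 of 24 suppressive or tumour-associated macrophage genes rose and 7 fell (7 and 9 adjusted over the list alone). Maf was among the former, and Gpnmb, Vegfa and Cd274 (−1.50), the ligand of PD-1, among the latter. Of 9 interferon response genes, 3 fell (4 adjusted over the list alone): Cd274, Cxcl10 (−1.40) and Rsad2 (−1.41). Of 13 inflammatory mediators, 3 fell (3 adjusted over the list alone): Il1rn (−1.42), Il1b (−1.36) and Il6 (−1.61). Of 11 chemokines, Ccl2 rose by 0.85 and 3 fell, among them Cxcl2 and Ccl3 (−1.61), with the same counts adjusted over the list alone. Of 9 genes of epithelial-mesenchymal transition, 3 rose, Twist1 (1.23), Twist2 (1.11) and Cdh2 (1.30), and Epcam fell by 1.09 (4 and 1 adjusted over the list alone). Both measured cell cycle genes rose, Mcm2 and Mki67 (1.71). Of 8 hypoxia genes, Ero1l rose by 0.91 and Vegfa fell, with the same counts adjusted over the list alone. Of the remaining list members that passed, Cd276 (0.96) and Nrp1 (0.82) rose, and H2-Eb1 (−0.72), Ccr7 (−1.39) and Tcf7 (−1.51) fell. No list passed camera in macrophage-like cells, the suppressive list having an adjusted p of 0.690. Arg1 (−0.19), Cxcl9 (−0.40), Foxp3 (−0.88), Gzmb (0.45) and Pdcd1 (−0.76) did not pass.

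Of these genes, 7 of the higher and 18 of the lower were spill-prone, the largest with at least 50 counts per sum being Mki67, Hmmr (1.58) and Il1r1 (1.31) among the former and Lrg1 (−2.08), Cd2 (−2.08) and Npnt (−1.64) among the latter. Of the 36 higher genes, 20 made up more of the transcripts of tumour-like cells in the tumour zone than of distant macrophage-like cells in both sections, Mki67 and Plau included. In 15 this held in neither section, among them Folr2, Cd72, Ms4a7, Maf and Mrc1, and for Il4ra in 1 section. Different clusters filled the class: cluster 13 gave 84.8% and 61.6% of macrophage-like cells in the tumour zone and 21.6% and 22.5% in the distant zone, and cluster 2 gave the rest. Mrc1, Cd72 and Ms4a7 were leading genes of cluster 13, and Marco, Gpnmb, Ctsk and Atp6v0d2 of cluster 2. A shift between these clusters would move these genes in the directions seen without a change within cells. Mean transcripts per cell were 94.0 and 78.2 in the tumour zone and 60.6 and 59.4 in the distant zone. Within cluster 2 alone 52 genes were called (40 shared), and within cluster 13 alone 0 were called by edgeR (84 at an unadjusted p under 0.05). The count was 75 with DESeq2 (64 shared) but 0 without the section term (85 at an unadjusted p under 0.05), 0 with the distant zone from 500 µm (57), 1 with a share of 0.3 and 3 with a minimum of 10 transcripts. It was 40 (37 shared) without cells within 10 µm of a tumour-like centre, and scaling to library size only gave 31 higher and 55 lower, with a median log2 over all genes of −0.22 against −0.12 with TMM. The sign turned for Folr2, Cxcl2, Cxcl10, Rsad2, Il1rn and Il1b with a share of 0.3, for Vegfa, Il1b and Nrp1 with a minimum of 10 transcripts, and for Ctsk and Il1rn in cluster 13 alone.

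In endothelial-like cells of the tumour zone 38 of 248 genes were higher and 35 lower than in distant lung (edgeR; 96 at an unadjusted p under 0.05). Tnfrsf9, a costimulatory receptor of the TNF family, rose by log2 2.56 (SE 0.40, adjusted p = 2.67e-08; 2.48 and 2.62). Egln3, an oxygen-sensing hydroxylase, rose by 2.43, the stress gene Ndrg1 by 1.81, the macrophage elastase Mmp12 by 2.32 (3.43 and 0.40), the checkpoint ligand Cd276 by 2.01, Fscn1 by 1.75, and Nusap1 and Mki67 by 2.07 and 2.05. The death receptor Fas fell by 2.45 (SE 0.41, adjusted p = 1.37e-07; −2.18 and −2.67). Cd24a fell by 2.43, the lipid droplet gene Hilpda fell by 2.39, the peptidase Dpp4 fell by 2.17, lipoprotein lipase Lpl fell by 2.05, Vegfa fell by 1.78, the shear-responsive factor Klf4 fell by 1.47 (−0.26 and −2.57) and Ido1 fell by 1.40.

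Of 8 hypoxia genes in endothelial-like cells, 5 rose, Egln3, Ndrg1 and Hif1a (1.39) among them, and Vegfa fell (6 and 1 adjusted over the list alone). Of 7 matrix genes, 4 rose (5 adjusted over the list alone), among them Plau (1.69), Acta2 (1.00) and Mmp13 (1.29). Of 9 genes of epithelial-mesenchymal transition, 5 rose (6 adjusted over the list alone), among them the transcription factors Twist1 (2.11), Twist2 (1.83) and Snai1 (1.34) and the hyaluronan receptor Cd44 (1.06). Of 9 interferon response genes, 4 fell (4 adjusted over the list alone), Cxcl10 (−2.00), Cd274 (−1.87), Ifit3 (−1.20) and Ido1. Of 8 tumour marker genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone). These 5 lists passed camera, each at an adjusted p of 0.0374. None held with an estimated correlation: adjusted p = 0.752 with an estimated correlation for the hypoxia, transition and tumour lists and 0.912 with an estimated correlation for the matrix and interferon lists. Other list members that rose were Il1rl1 (1.83), Pgf (1.53), Cd80 (1.46), Mcm2 (1.46), Ccl2 (1.05), Casp8 (0.93) and Cxcr4 (0.90), and others that fell were Ccl22 (−2.69), Marco (−2.58), Ccr7 (−1.51), Ltb (−1.49), H2-Eb1 (−1.36) and Gata3 (−1.35). Mrc1 (0.95), Arg1 (0.72), Gzmb (0.19), Cxcl9 (−0.06), Foxp3 (−0.73) and Pdcd1 (−0.74) did not pass.

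In endothelial-like cells 13 of the higher and 24 of the lower genes were spill-prone, the largest with at least 50 counts per sum being Twist1, Hmmr (1.90) and Fgfr1 (1.87) among the former and Cbr2 (−2.55), Cxcl10 and Ighm (−1.94) among the latter. Of the 38 higher genes, 31 made up more of the transcripts of tumour-like cells than of distant endothelial-like cells in both sections. This held in 1 section for Acta2, Col15a1, Egln3 and P2ry2 and in neither for Cxcr4, Pgf and Plac8. Of the lower genes, Cd24a and Vegfa were leading genes of the unnamed clusters 14 and 16, which the spill rule left out. Mean transcripts per cell were 86.6 and 84.3 in the tumour zone and 44.3 and 37.9 in the distant zone. Cluster 18, with Klf4 and Fas among its leading genes, gave 7.38% and 9.79% of endothelial-like cells in the distant zone and 0% and 0.245% in the tumour zone, and cluster 3 gave the rest. Within cluster 3 alone 75 genes were called (72 shared), with Klf4 at −1.31 and Fas at −2.36. All but 1 of the 73 genes had the same direction in both sections. DESeq2 called 58 genes (56 shared), a minimum of 10 transcripts gave 42 (37 shared), and the fit without the section term gave 19 (all shared), 11 higher and 8 lower. The sign turned for Ido1, Cxcl10 and Cxcl9 with a share of 0.3 and for Ido1 with a minimum of 10 transcripts.

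In the neutrophil-like class 3 genes were higher and 2 lower of 272 in the tumour zone (edgeR; 82 at an unadjusted p under 0.05). Ctsk, the protease cathepsin K, rose by log2 3.29 (SE 0.25, adjusted p = 0.00215; 3.60 and 2.94). The gelatinase Mmp9 rose by 2.66 (adjusted p = 0.0107; 3.13 and 2.14) and Dcstamp, a cell fusion protein of osteoclasts, by 2.83 (adjusted p = 0.0300; 3.30 and 2.30). The interferon-induced genes Cxcl10 and Rsad2 fell by 1.93 and fell by 1.17 (both adjusted p = 0.0458). The interferon response list was lower as a whole (camera adjusted p = 0.000623), with 2 of its 9 genes past the threshold and 7 adjusted over the list alone. The adjusted p was 0.763 with an estimated correlation. Cd274 (−0.88), Vegfa (−0.93), Cxcl9 (−1.19), Gzmb (−0.999), Foxp3 (−0.56), Pdcd1 (−0.73), Arg1 (0.11), Mki67 (0.84) and Mrc1 (0.85) did not pass. None of the 3 higher genes made up more of the transcripts of tumour-like cells than of distant neutrophil-like cells in either section.

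The 3 higher genes of the neutrophil-like class were leading genes of a small population that lay mostly within it. With a minimum of 50 transcripts an unnamed cluster of 277 cells led by Mmp9, Ctsk, Atp6v0d2 and Dcstamp stood apart. It held 195 cells that were neutrophil-like in the main setting: 21 of 105 in the tumour zone and 24 of 1470 in the distant zone of section 1, and 40 of 804 and 13 of 2632 in section 2. Without these cells Ctsk still rose, by 1.41, and Mmp9 (0.44) and Dcstamp (0.20) did not pass, while Cxcl10 and Rsad2 fell by 1.83 and fell by 1.07, and 26 genes were called (3 shared). As Ctsk, Mmp9 and Dcstamp lead that cluster, its removal lowers them by construction. Of the 9390 cells of the class, 4587 (48.8%) had under 50 transcripts. These could not be assigned to the cluster and stayed in, so the source of the remaining rise of Ctsk is open. At resolution 2.0, 6500 of the 9390 cells of the class (69.2%) were named monocyte-like and 2229 (23.7%) neutrophil-like. In the former Cxcl10 fell by 1.99 and Rsad2 fell by 1.21, while Ctsk (1.08), Mmp9 (0.34) and Dcstamp (0.94) did not pass. With volume scaling no cluster was named neutrophil-like, and 66.0% of these cells were dendritic-like. DESeq2 called 18 genes, all 5 among them, a share of 0.3 gave 40 (3 shared), a minimum of 10 transcripts 18 (2 shared), library size only 3 higher and 7 lower with a median log2 of −0.27 against −0.06, and a minimum of 50 transcripts 1, with Dcstamp at −0.64. Without the section term edgeR called 0 (56 at an unadjusted p under 0.05), and with wider tumour zones it called 2, of which 1 was shared.

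Dendritic-like cells of the tumour zone differed in 4 of 279 genes (edgeR; 69 at an unadjusted p under 0.05). Mmp12 rose by log2 2.10 (SE 0.38, adjusted p = 0.00825; 2.56 and 1.60) and the tetraspanin Cd9 by 1.096 (adjusted p = 0.0374; 1.14 and 1.05). Cxcl10, which attracts T cells, fell by 1.72 (SE 0.30, adjusted p = 0.00825; −2.10 and −1.41), and the spill-prone T-cell gene Cd4 fell by 2.64 (adjusted p = 0.0172). As whole lists, hypoxia genes were higher (camera adjusted p = 0.00531), and genes of lymphoid aggregates (0.00122), T-cell markers (0.000432), B-cell markers and interferon response genes (0.0139 each) were lower. For each of these lists the adjusted p was 0.909 with an estimated correlation. Adjusted over the list alone, 4 of 8 hypoxia genes were higher, and 6 of 16 aggregate genes, 5 of 20 T-cell markers, 5 of 11 B-cell markers and 2 of 9 interferon genes were lower. Arg1 (1.18), Mrc1 (0.69), Mki67 (0.66), Cd274 (−0.59), Cxcl9 (−1.27), Vegfa (−0.42), Foxp3 (−0.47), Gzmb (−0.70) and Pdcd1 (−0.33) did not pass. Cluster 19, led by Ccr7, gave 14.4% and 1.37% of dendritic-like cells in the tumour zone and 7.47% and 8.78% in the distant zone. Of the 2 higher genes, 1, Cd9, made up more of the transcripts of tumour-like cells in both sections, and Mmp12 in 1. DESeq2 called 3 genes, and edgeR called 0 without the section term (31 at an unadjusted p under 0.05), with the distant zone from 100 µm (58), with a minimum of 50 transcripts (51), within 3 µm of the centre (66) and without cells within 10 µm of a tumour-like centre (35). A minimum of 10 transcripts gave 46, a share of 0.3 and wider tumour zones 29 each, and library size only 1 higher and 8 lower, with a median log2 of −0.24 against −0.05.

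T-like cells had no gene past the threshold among 274 (edgeR; 73 at an unadjusted p under 0.05, smallest adjusted p 0.0554), and DESeq2 called 24, 13 higher and 11 lower. The largest of the fixed set was Cxcl9, a ligand that attracts T cells, at log2 −1.79 (SE 0.28, adjusted p = 0.0554; −2.00 and −1.66). The inhibitory receptor Pdcd1 had 0.64 (adjusted p = 0.0993; 0.55 and 0.72), the cytotoxic protease Gzmb 0.65 (−0.33 and 1.56), Foxp3 of regulatory T cells 0.18 and Mki67 0.72. Arg1 had 1.15, Mrc1 0.85, Vegfa −1.40 and Cd274 −0.64. Cxcl9 was a leading gene of unnamed cluster 17, with 25 and 68 cells in the tumour zone and 499 and 385 in the distant zone. Arg1 and Mrc1 were leading genes of macrophage-like clusters, and Vegfa of unnamed cluster 16. RNA of these cells may enter the values of T-like cells, which was not tested. As a list, interferon response genes were lower (camera adjusted p = 0.00746; 3 of 9 adjusted over the list alone), genes of epithelial-mesenchymal transition higher (0.0180; 2 of 9) and B-cell markers lower (0.0416; 1 of 11), with an adjusted p of 0.663 with an estimated correlation for each. Of 274 genes, 185 had the same direction in both sections. EdgeR called 82 genes with wider tumour zones, 59 with a share of 0.3, 25 within 3 µm of the centre, 22 with a minimum of 10 transcripts, 18 without cells within 10 µm of a tumour-like centre and 1 at equal depth.

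**Figure D3:**
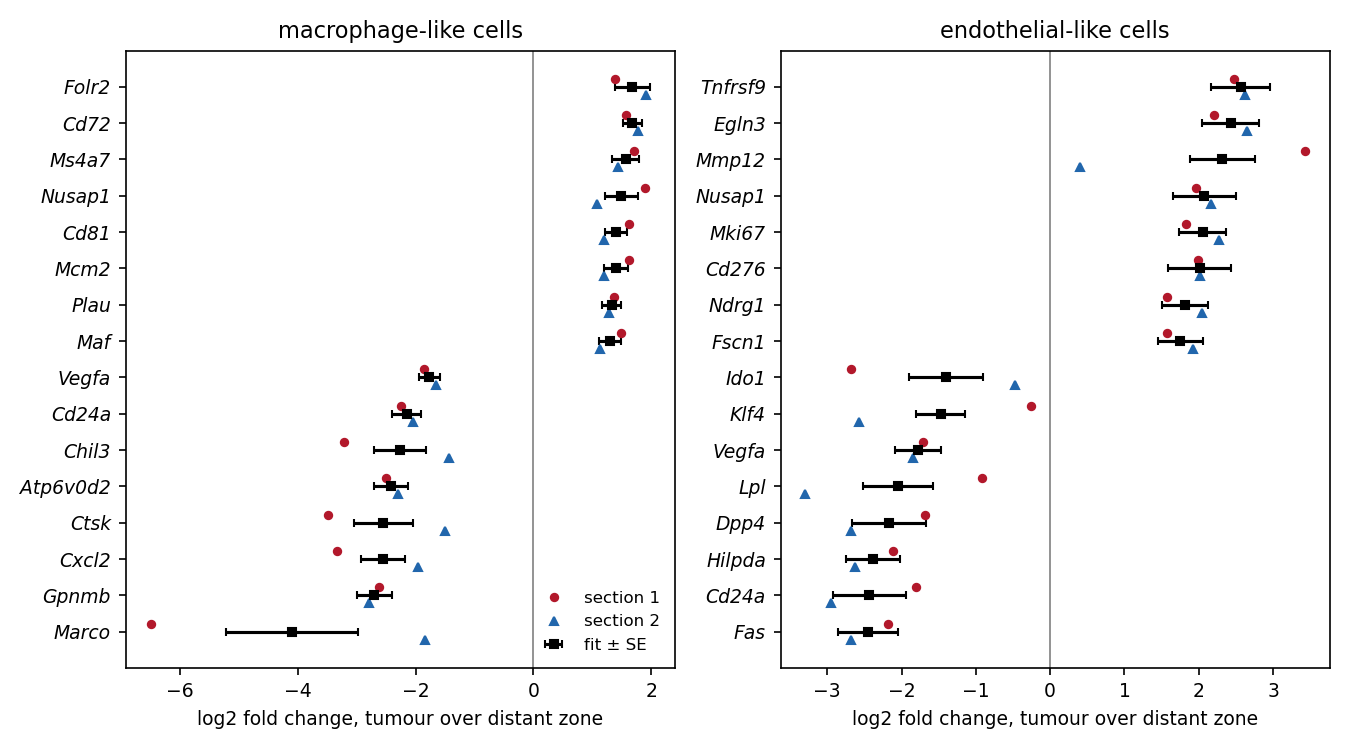
Log2 fold change, tumour zone over distant zone, (horizontal axes) of the 8 genes with the largest change in each direction, among those past the threshold, with at least 50 counts per sum, the same direction in both sections and not spill-prone, in macrophage-like (left) and endothelial-like cells (right), with squares for the edgeR fit, bars for its standard error, circles for section 1 and triangles for section 2. The sections lie far apart for Marco (−6.50 and −1.84) and for endothelial Mmp12 (3.43 and 0.40) and close together for Gpnmb (−2.63 and −2.79).

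Tumour-like cells of the core and of the rim showed no gene past the threshold among 281 (edgeR; 1 at an unadjusted p under 0.05, and DESeq2 also 0). The gene with that p was Egr1, an immediate early gene, at −3.08. The core held 153 cells in section 1 and 13 in section 2, against 3441 and 6558 in the rim, and the core of section 2 held 1126 transcripts. In simulated sums of this depth 30% of genes changed by 4-fold were recovered. With a rim of 50 µm the core held 1091 and 1583 cells, and edgeR called 0 genes of 286 (25 at an unadjusted p under 0.05). With unnamed clusters of tumour profile counted as tumour, the core held 5750 and 1024 cells and edgeR called 23 genes, 9 higher and 14 lower.

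Around tumour-like cells, dendritic-like and neutrophil-like cells were more frequent in both sections than random placement within zones would give. Both names depend on the settings. At resolution 2.0, 69.2% of the neutrophil-like cells were monocyte-like, and with volume scaling 66.0% were dendritic-like. Within 30 µm dendritic-like cells had a log2 ratio of observed to expected pairs of 0.27 ± 0.08 (SD, n = 2; 0.33 and 0.22) and neutrophil-like cells 0.23 ± 0.06 (0.28 and 0.19). B-like cells lay at −1.11 ± 0.44 (−1.43 and −0.80), endothelial-like cells at −0.35 ± 0.09, alveolar type 2-like cells at −0.33 ± 0.32 and fibroblast-like cells at −0.32 ± 0.06. T-like cells (0.06 ± 0.09) and macrophage-like cells (0.02 ± 0.01) lay near 0, and tumour-like cells had 0.31 ± 0.15 among themselves. Within 15 µm macrophage-like cells turned to −0.12 and T-like cells to −0.05. Relabelling over the whole section took T-like cells to −0.29 and dendritic-like cells to 0.06, and neutrophil-like cells to −0.0058 in section 1 and 0.43 in section 2.

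**Figure D4:**
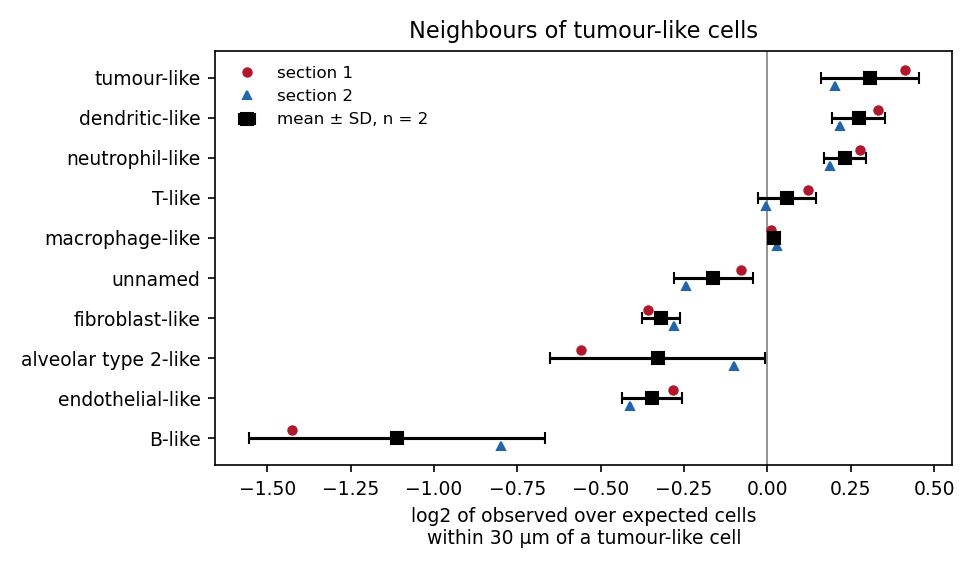
Log2 ratio of observed to expected pairs with tumour-like cells within 30 µm (horizontal axis) per cell type, with squares for the mean, bars for the SD (n = 2), circles for section 1 and triangles for section 2. Dendritic-like cells lie highest among the other named types at 0.27, and B-like cells lowest at −1.11.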

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

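No test in this part was chosen after its result was seen. The detected transcripts that the segmentation placed in no cell were examined because no comparison uses them and their number is far above a count of 0. They numbered 10216456 in section 1 and 13211174 in section 2, which is 70.3% and 68.5% of all gene transcripts detected. The cells under 20 transcripts were examined for the same reason and numbered 68793 in section 1 and 82478 in section 2.

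False decoding as the source of the transcripts outside cells would raise the share of blank barcodes there. That share was 0.522% outside and 0.485% inside cells in section 1 and 0.543% and 0.502% in section 2, at most 1.08 times as high outside, which argues against it. Cell bodies that the segmentation missed or trimmed would leave the gene makeup outside cells like that inside. Spearman rho across genes, which are not independent replicates, was 0.994 in both sections. Missed or trimmed cell bodies are therefore a candidate source, though RNA displaced from cells, which was not tested, may give the same makeup. No biological explanation was tested.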

How the results depend on the processing

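The settings chosen after seeing the data were tumour zones with the unnamed clusters of tumour profile, a share among all kept cells, a library of named types only, removal of cells within 10 µm of a tumour-like or tumour-profile centre, each macrophage-like and endothelial-like cluster alone, and neutrophil-like cells divided by their class under other settings. B-like cells stayed lower, past the threshold, under all settings with a test of cell numbers, from −5.70 to −3.12 in the tumour and from −3.62 to −1.94 in the margin. Of 2239 values of named genes between tumour and distant zone under other settings, 1749 kept their direction and side of the threshold, 429 kept the direction and missed it, 44 passed it newly and 17 reversed; for core against rim these were 66 unchanged and 2 newly past it of 68. A change of sign where neither setting passed the threshold was counted as unchanged. The core of section 2 held 13 cells. For the changes below the cause was not tested.

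A minimum of 10 transcripts gave shares of 3.14% (B-like), 8.84% (T-like), 6.45% (dendritic-like), 12.2% (endothelial-like) and 5.24% (fibroblast-like), 8 nodules and 0.815 mm² per section (0.381 mm² in section 1 and 1.25 mm² in section 2), 2 types higher and 3 lower in the tumour and likewise in the margin, and 22 (T-like), 40 (alveolar type 2-like), 46 (dendritic-like), 42 (endothelial-like), 3 (macrophage-like) and 18 (neutrophil-like) genes. Neutrophil-like cells, then with a further cluster of 4704 cells, turned to 1.48 in the tumour, dendritic Vegfa to 1.08, endothelial Ido1 to 0.49, and macrophage Vegfa, Il1b and Nrp1 to 0.15, 0.52 and −0.20. A minimum of 50 gave 1.41% B-like, 6.20% T-like, 6.49% endothelial-like, 2.75% fibroblast-like and 24.8% tumour-like cells, 3 nodules, 1.20 mm², and 4 (alveolar type 2-like), 0 (dendritic-like) and 1 (neutrophil-like) genes, with neutrophil Dcstamp at −0.64 and 277 cells led by Mmp9 and Ctsk in an unnamed cluster of their own. Without those, 26 neutrophil genes were called, and 3 in the neutrophil-like cells named monocyte-like at resolution 2.0. Resolution 0.5 gave 8.66% fibroblast-like, 34.1% tumour-like (39.0% in section 1 and 29.2% in section 2) and 5.39% unnamed cells, and resolution 2.0 gave 6.22% T-like, 1.60% neutrophil-like and 16.6% tumour-like cells, with 5.13% monocyte-like, a type absent from the main setting. Plasma-like cells, also absent from the main setting, made up 0.764% at resolution 2.0 and 0.587% at a minimum of 50 transcripts. Volume scaling gave 2.97% B-like, 4.65% T-like, 11.1% dendritic-like and 6.57% fibroblast-like cells. No cluster was named neutrophil-like there, and of the cells that were so in the main setting 66.0% were dendritic-like.

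A share of 0.3 gave 2 nodules and 3.10 mm² per section, 1 type higher and 3 lower in the tumour, 2 and 3 in the margin, and 59 (T-like), 4 (alveolar type 2-like), 29 (dendritic-like), 31 (fibroblast-like), 1 (macrophage-like) and 40 (neutrophil-like) genes. It reversed endothelial Ido1 (0.88), Cxcl10 (0.092) and Cxcl9 (1.84) and macrophage Folr2 (−0.027), Cxcl2 (0.0086), Cxcl10 (0.50), Rsad2 (0.076), Il1rn (0.019) and Il1b (0.60). A share of 0.7 gave 1 nodule and 0.0508 mm² per section, with none in section 2. Smoothing over 15 µm gave 7.5 nodules and 1.19 mm², over 60 µm 3.5 nodules and 1.01 mm², and the share among all cells 0.422 mm² (0.0809 mm² in section 1 and 0.762 mm² in section 2). Wider tumour zones gave 2.54 mm², 2 types higher and 2 lower in the tumour, 3 and 3 in the margin, and 82 (T-like), 43 (alveolar type 2-like), 29 (dendritic-like), 40 (fibroblast-like) and 2 (neutrophil-like) genes, and 23 in core against rim. They gave 8 (T-like), 0 (fibroblast-like), 1 (macrophage-like) and 6 (neutrophil-like) gene lists, neighbour ratios of −0.067 (T-like), 0.12 (dendritic-like), −0.25 (fibroblast-like) and −1.60 (unnamed), neutrophil-like cells at 1.12 in the tumour and dendritic-like cells at 0.93 in the margin. A distant zone from 100 µm gave 33 (alveolar type 2-like), 0 (dendritic-like), 27 (fibroblast-like) and 11 (neutrophil-like) genes, and from 500 µm 13 (alveolar type 2-like), 7 (fibroblast-like) and 0 (macrophage-like).

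For cell numbers, TMM factors gave 1 type higher in the tumour and 2 higher and 2 lower in the margin. The library of named types gave 1 higher in the tumour and 1 higher and 3 lower in the margin, all cells as the library 7 lower in the tumour and 3 in the margin, zone area 1 higher in the margin, and DESeq2 3 lower in each. Tumour-like cells, which define the tumour zone, count in the library of all cells and so lower the other types there. For genes, DESeq2 gave 24 (T-like), 31 (fibroblast-like) and 18 (neutrophil-like), library size only 9 (dendritic-like) and 10 (neutrophil-like), and no filter 31 each (alveolar type 2-like and fibroblast-like). Equal depth gave 1 (T-like), 8 (fibroblast-like) and 15 (neutrophil-like), and transcripts within 3 µm of the centre 25 (T-like), 12 (alveolar type 2-like), 0 (dendritic-like), 35 (fibroblast-like) and 20 (neutrophil-like). Removal of cells within 10 µm of a tumour-like centre gave 18 (T-like), 0 (alveolar type 2-like and dendritic-like) and 40 (macrophage-like), and of a tumour-profile centre also 0 (alveolar type 2-like) and 40 (macrophage-like). Cluster 13 alone gave 0 macrophage genes and turned Ctsk to 0.55 and Il1rn to 0.22. With no replicate block, the fit without the section term, 0 genes were called in alveolar type 2-like, dendritic-like, macrophage-like and neutrophil-like cells, 19 in endothelial-like and 1 in fibroblast-like cells, and 4 lists in neutrophil-like cells. An estimated correlation gave 0 lists in each type.

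Neighbour ratios within 15 µm were −0.049 (T-like), −0.72 (alveolar type 2-like), 0.19 (dendritic-like), −0.59 (endothelial-like), −0.44 (fibroblast-like), 0.16 (neutrophil-like) and, reversed, −0.12 (macrophage-like). Within 50 µm they were −0.25 (fibroblast-like) and 0.065 (macrophage-like). Relabelling over the whole section gave −2.19 (B-like), −0.29 (T-like), 0.057 (dendritic-like), −0.0058 and 0.43 in section 1 and section 2 (neutrophil-like), −0.87 (endothelial-like), −0.88 (fibroblast-like), 0.22 (macrophage-like) and 1.03 (tumour-like).

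Some settings could not be run. Without cells that have a tumour-like centre within 15 µm, every type fell under 50 cells in a sum. A rim of 150 µm left no core cells, and a share of 0.7 left section 2 without a tumour zone to compare. Some types had too few cells to be tested: fibroblast-like at a minimum of 10 transcripts, fibroblast-like and neutrophil-like without cells near tumour-like centres, and T-like and dendritic-like too without those near tumour-profile centres. The cells still neutrophil-like at resolution 2.0 had too few as well, 36 in the tumour zone of section 1, as had endothelial-like cluster 18. B-like cells had too few for any gene test.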

Other observations

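The settings with wider tumour zones and without cells near tumour-like or tumour-profile centres were chosen after seeing the data, as was the test of single genes against the level of tumour-like cells, and the other tests of mixing at any distance came after the values without such cells, before their own. With unnamed clusters of tumour profile counted as tumour, 23 genes differed between core and rim (edgeR; 5750 and 1024 core cells). Lower in the core were mediators of inflammation, Nos2 (−1.88), the granulocyte factor Csf3 (−1.55), Ptgs2 (−1.34), Il1rn (−1.24), Il1b (−0.997) and the monocyte attractant Ccl2 (−0.68), and the interferon-induced chemokines Cxcl9 (−1.40) and Cxcl10 (−1.37). Higher were the stromal genes Lrrc15 (1.00) and Pdgfra (0.79), with Nrp1 (0.96), Cacnb3 (0.95) and Tcf4 (0.84). As lists, inflammatory mediators (5 of 14 lower, 6 adjusted over the list alone; camera adjusted p = 0.000376), interferon response genes (2 of 9, 2 adjusted over the list alone; 0.00355) and chemokines (4 of 11, 4 adjusted over the list alone; 0.0196) were lower, each with an adjusted p of 0.988 with an estimated correlation. Different clusters filled core and rim: cluster 12, led by mediators of inflammation, gave 3.86% and 0.684% of the core cells of section 1 and section 2 and 15.1% and 5.23% of the rim cells, and cluster 8 gave 53.1% of the core and 34.0% of the rim of section 1. Cluster 11, with Tcf4, Pdgfra, Cacnb3 and Nrp1 among its leading genes, gave 46.8% of the core and 19.6% of the rim of section 2 but 2.07% and 4.93% in section 1, and cluster 1 gave 42.2% of the core and 66.8% of the rim of section 2. The values thus compare mixtures of clusters, and no test within 1 cluster was run. Clusters 8 and 11, with stromal genes among their leading genes, may not be tumour.

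Among cell pairs within 30 µm, T-like and dendritic-like cells were found together more often than random placement within zones gives (log2 0.59 ± 0.03, SD, n = 2), as were dendritic-like and neutrophil-like cells (0.46 ± 0.13) and T-like and neutrophil-like cells (0.35 ± 0.16). Dendritic-like cells were found less often beside B-like (−0.63 ± 0.13) and endothelial-like cells (−0.62 ± 0.12). The dendritic-like and neutrophil-like classes were not sharply apart, since with volume scaling 66.0% of the latter were named dendritic-like. Alveolar type 2-like cells had 12 of 267 genes higher and 8 lower in the tumour zone. Of these, 7 of the higher and 4 of the lower were spill-prone, and 6 of those 7 were highest in tumour-like cells. Mixed-in tumour-like RNA was not tested for this type. Hypoxia genes were higher as a list in alveolar type 2-like cells (camera adjusted p = 0.00502, 0.846 with an estimated correlation, 6 of 8 adjusted over the list alone). Genes of epithelial-mesenchymal transition (0.00502; 4 of 9), matrix (0.0242; 2 of 7) and tumour markers (0.0131; 4 of 8) were higher too. Interferon genes (0.0341; 2 of 9), B-cell (0.0351; 3 of 10) and endothelial markers (0.0341; 3 of 4) were lower, all with an adjusted p of 0.846 with an estimated correlation. Fibroblast-like cells had 4 genes higher and 10 lower of 205, and the list of epithelial-mesenchymal transition was higher (camera adjusted p = 0.0309, 1 of 9), with an adjusted p of 0.851 with an estimated correlation. Of the fibroblast-like genes, 2 of the 4 higher, both highest in tumour-like cells, and 6 of the 10 lower were spill-prone. Mixed-in tumour-like RNA was not tested for them either. EdgeR called 0 genes in alveolar type 2-like cells without the section term (31 at an unadjusted p under 0.05) or without cells near tumour-like centres (40), while DESeq2 called 21.

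Genes were higher in other cell types inside the tumour zone, 79 in the 5 described types, and tumour-like transcripts counted in touching cells could be a source. Without cells within 10 µm of a tumour-like centre the median log2 change was 1.07 times that with all cells (76 genes, all still higher). Within 3 µm of the cell centre it was 1.01 times, and without cells near tumour-like or tumour-profile centres 1.05 times (73 genes, all still higher). These values argue against kept tumour-like cells with a centre within 10 µm as the source, for distances along x and y. All image planes were pooled, so RNA from above or below a cell was not addressed. Cells under 20 transcripts and transcripts outside cells have no type, so tumour RNA from these could not be excluded. The values do not settle contact at 10 to 15 µm either, since removal at 15 µm left too few cells to test. Of macrophage-like cells in the tumour zone, 267 and 301 were left by removal at 10 µm, and 78 and 38 by removal at 15 µm. Mixing at any distance can raise a gene only where tumour-like cells carry relatively more of it, which held in both sections for 0.658 of the 79 genes (52), in 1 section for 6 and in neither for 21, among them macrophage Folr2, Maf, Mrc1, Cx3cr1 and C1qa and neutrophil Ctsk. At the mean level of the named tumour-like cells, mixing could not give the rise of these 21. Nor could it for 3 of the other 58, endothelial Ndrg1, Acta2 and Col15a1. In both sections these lay above the level of tumour-like and of their own distant cells by more than counting error. The unnamed clusters of tumour profile did not enter that level. Among them cluster 12, with Ndrg1 as a leading gene, had 237 and 257 cells in the tumour zone. A change in the cells, a change in which cells fill the class, and RNA of other cells, those clusters included, remain open for all these genes. For the 52, abundant tumour-like genes needed 0.685 of the mixed-in share that the higher genes needed, just above the bound of 0.67 set for mixing, so mixed-in tumour-like RNA remains a candidate source for genes such as Mki67.

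Tumour-like cells of section 1 carried more Mmp12 (log2 −4.05 for section 2 over section 1), Lrrc15 (−3.63), Plau (−1.34) and Mki67 (−1.34), and those of section 2 more of other genes such as Ly6a, Egln3 and Ifit1. A section-wide difference in detection would move the same genes alike in other cell types of the distant zone, by at least 0.5 of the difference. The 34 genes used were picked for a log2 difference of at least 1 and a minimum level in tumour-like cells, a choice that favours a low fraction. Over these genes the median was 0.181 of the difference (95% interval 0.0820 to 0.306), with 29 genes in the same direction. Within that limit this argues against detection as the whole cause. The median over those types was −1.50 for Mmp12, −0.040 for Lrrc15, −0.52 for Mki67 (−0.76 with the types pooled) and −1.05 for Plau (−1.18 pooled), and 8 of the 34 genes reached 0.5 by either measure, so detection stays open for these, Plau, Mki67 and Ifit1 among them. Separate tumours, which may differ in growth, remain possible, and no biological explanation was tested, since the labels give the sections no difference.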
